A study of Drosophila melanogaster with 2 samples.

How the data were processed

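Chromatin immunoprecipitation followed by sequencing with an antibody against trimethylated lysine 27 of histone H3 (H3K27me3), the mark placed by the Polycomb machinery, was analysed in whole Drosophila melanogaster ovaries. The series held 2 libraries. One came from flies of strain W1118, labelled wild type, and the other from flies labelled piwi1/2, mutant in the gene for the PIWI-family Argonaute protein Piwi. Per the labels' protocols, flies were kept at 20 °C, more than 50 pairs of ovaries were homogenised, and the extract was made with a buffer holding 300 mM KCl. That protocol describes proteins eluted from beads in loading buffer and no shearing of chromatin, so whether it is the preparation of these libraries is not clear. No input or control antibody library was analysed here.

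For each library the deposited file lists distinct reads of 50 nt with the counts of how often the authors sequenced each, and per the file headers these values are read numbers. The deposited counts carry no alignment position and no normalization. The genome build dm3 and the peak caller MACS are named per the submitters' processing notes. The aligner, its settings and any filter on the reads before deposit are not given in the sources used here. No peak list was analysed here.

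The reads had to be placed on a sequence before any locus could be measured, and no genome was provided for the series. The only stretch of the dm3 build at hand was the set of sequences lying 2 kb upstream of RefSeq transcript starts that ships with the R package Biostrings (version 2.70.1). This set holds 26454 sequences, 26452 of them of full length, for 26259 RefSeq accessions. The accessions were matched to gene symbols through the RefSeq gene table, whose assembly is Release 6 plus ISO1 MT and whose coordinates were not used. In all, 25653 accessions matched, giving 12599 symbols and 17388 windows. Overlapping windows were merged into 9031 stretches with a total length of 25262688 bp. All coordinates are dm3, counted from 1. Gene bodies, introns and regions far from a transcript start were not measured.

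A read was placed where either its first or its last 25 nt matched exactly, with at most 2 mismatches over the 50 nt, on either strand, and was used when it had 1 such place in the set. Uniqueness was judged within the set and not over the genome, so a read from an unmeasured copy of a repeat can be placed wrongly. Reads made of a tandem repeat with a period of up to 12 nt and at most 2 mismatching steps were set aside. Steps of 50 bp were masked when they held over 400 reads summed over both libraries, when at least 20% of 20 or more reads carried 2 mismatches, or when at least 20% of their reads, and at least 5, had several places. The mask covered 2.26% of the bases but took a larger and unequal part of the placed reads. It left 4656406 of 6226986 in the wild type-labelled and 3325504 of 5386976 in the mutant-labelled library. The matching was done in Python 3.11.15 with numba 0.67.0, numpy 2.4.6 and pandas 2.3.3. Intervals used scipy 1.17.1, the trend fit used statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. Arm lengths came from GenomeInfoDb 1.38.1.

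The design written before the data were examined called for bins of 5 kb and gene spans extended by 1 kb. Gene spans lie outside the upstream sequence, and a 5 kb bin would be filled only in part by most merged stretches, so 5 kb, the planned size, and 10 kb serve as alternatives in which a stretch is divided at up to that length. The merged stretches were therefore divided into pieces of about 2 kb, and each gene was measured in its 2 kb upstream window, taking the window with the most reads per kb where a gene has several. Pieces with fewer than 50% of their bases unmasked, and windows with under 1000 unmasked start positions, were left out. The level of a piece or window is its reads per unmasked kb divided by the median piece of the same library. A piece was called enriched at 3 or more times that median, and enriched pieces next to each other and no more than 20 kb apart were joined into domains.

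The log2 ratio of a window is the mutant-labelled over the wild type-labelled read count after scaling by the totals on arms 2L, 2R, 3L, 3R, X and 4, with an exact conditional binomial interval at 95%. Windows with under 200 reads over both libraries were not called. A gene was called above 0.5 or below -0.5 when its ratio passed that value and its interval excluded 0. With 1 library per group there was no replicate check, so no p-values were computed, and every interval covers counting error only, since reads made by PCR are not independent molecules. The median ratio of each gene list was set against 10000 random lists of the same size drawn from the 100 genes nearest in level to each member, as a description of these 2 libraries.

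Fixed before the data were examined were 14 gene lists, 1 of them the label checks piwi, w and ry. The others were homeotic genes, developmental regulators under Polycomb control, Polycomb group genes under Polycomb control, Polycomb and Trithorax group genes, germline stem cell and oogenesis genes, piRNA pathway genes, ovarian somatic and follicle cell genes, chorion and vitelline membrane genes, testis genes, neuronal genes, muscle genes, housekeeping genes and heat shock genes. Of the names listed, Caf1, calypso, nos, Notch, rye, RpII215, Ald and Sod matched no single symbol and were left out. Genes to be named were fixed by rule as well. The rule took the label checks, the 2 highest and 2 lowest members of each list by log2 ratio and the 2 members with the highest wild type level, the 15 highest and 15 lowest genes with at least 200 reads and no more extreme gene within 20 kb, and the gene of highest level in each of the 10 widest domains of each library. Members that the rule gave and the text does not print stand in the counts. Genes named outside this rule are said to be so.

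The matching was tested on 20000 simulated reads from the set. Of 5000 reads with no mismatch 98.2% were placed, of 5000 with 1 mismatch 98.6%, and of 5000 with 2 mismatches 48.1%, because a read with a mismatch in each of its 25 nt ends has no exact seed. At least 99.96% of the placed reads of these kinds lay at their true position. All simulated reads came from the set, so wrong placement of reads from outside it was not tested. The gene ratio was tested on simulated counts for 11777 genes, 200 of them changed. All 50 genes with a true fold of 2 and all 50 with a fold of 0.5 were called, 76% of those with a fold of 1.5 and 72% of those with a fold of 0.67. Of 11577 unchanged simulated genes 0.16% were called, and 95.6% of their intervals covered the true ratio. The simulated counts carried counting error only, which is what the interval is built for, so this coverage checks the calculation alone. PCR duplicates and variation between replicates were not simulated, so these gene rates do not give the share of false calls in the real libraries.

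Alternatives listed before the data were examined were thresholds of 2 and 5 times the median, pieces of up to 10 kb, 1 read per position and strand, thinning of the deeper library, scaling by the pieces enriched in neither library or by the reads in enriched pieces, no read minimum, a pseudocount of 10 reads, log2 values for the correlation, and a domain-based overlap. Added after the data were examined were pieces of 1 kb, pieces of 5 kb as an alternative to the 2 kb in use (5 kb being the size planned at first), reads with no mismatch, no repeat mask, all windows of a gene together, and the difference from a lowess trend (fraction 0.3) of the ratio with the level.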

Results

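H3K27me3 was profiled in ovaries of flies labelled wild type and of flies labelled piwi mutant, with 1 library in each group, to compare the sites of the mark between them. The wild type-labelled library held 46800848 reads of 30925744 distinct sequences and the mutant-labelled library 44898799 reads of 26177941 distinct sequences, all of 50 nt. In sequence lying 2 kb upstream of annotated transcripts, 6226986 reads (13.3%) and 5386976 reads (11.998%) had a single place. After masking of repeats, 4625972 and 3296320 reads remained on the main chromosome arms, with a mean of 1.26 and 1.27 reads per occupied position and strand. With 1 library per group no difference below could be set against a replicate, and intervals cover counting error only.

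The window upstream of piwi, the gene named by the mutant label (2L:10987417-10989416), held 165 reads in the wild type-labelled library and 66 in the mutant-labelled library, a log2 ratio of -0.83 (95% interval -1.27 to -0.41). A mutation within the gene would leave this window in place, so its reads do not check the label. Upstream of w, the white eye colour gene (X:2690500-2692499), the counts were 128 and 6, at levels of 0.454 and 0.0366 times the library medians. The log2 ratio was -3.93 (-5.40 to -2.76), from fewer reads than the minimum for a call. The strain label W1118 refers to a white allele that is known to lack part of this gene, yet the near-empty window belonged to the library labelled piwi1/2. Whether that deletion reaches this window was not tested, and the directions given below rest on the labels as deposited. Upstream of ry, the gene of the rosy eye colour locus, 290 and 84 reads gave a ratio of -1.30 (-1.67 to -0.94).

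The question of which sites carry the mark in each library was asked over 12567 pieces of about 2 kb. Nearly all sites enriched in the wild type-labelled library were enriched in the mutant-labelled library too. At this piece size and a threshold of 3, fewer than 50% of those of the mutant-labelled library were enriched in the other. That share depended on the setting, with 56.5% for the planned 5 kb bins, 62.5% at 2 times the median and 36.4% with 1 read per position and strand. Of the 583 pieces enriched at least 3 times over the median in the wild type-labelled library, 580 (99.5%) were enriched in the mutant-labelled library too, where 1258 pieces passed, 46.1% of them shared. Lists of these lengths drawn independently would share 58.4. The 678 pieces enriched only in the mutant-labelled library were mostly sites of intermediate level in the other, 606 of them at 2 to 3 times the median and 6 below the median. Their median level was 2.498 in the wild type-labelled and 3.48 in the mutant-labelled library. The 3 pieces enriched only in the wild type-labelled library included the one upstream of Map205, described below.

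The share of reads in each library's own enriched pieces was 17.6% (exact binomial interval 17.5 to 17.6%) in the wild type-labelled and 37.5% (37.4 to 37.5%) in the mutant-labelled library. In pieces enriched in either library the shares were 27.3% and 37.5%. All but 3 of these pieces were enriched in the mutant-labelled library, so this set too favours the share of that library. The difference grew with the level. The 893 pieces under 0.5 times the median in the wild type-labelled library had a median of 0.418 there and of 0.309 in the mutant-labelled library. For the 366 pieces at 3 to 5 times the median these values were 3.55 and 5.28, for the 129 pieces at 5 to 8 times they were 6.23 and 11.6, and for the 14 pieces above 12 times they were 12.8 and 27.1. Across pieces, which are not independent replicates, Pearson's r between libraries was 0.964 and Spearman's rho 0.953. Random splits of the reads of one library into equal parts gave r of 0.993 and rho of 0.971 in the wild type-labelled library, and 0.996 and 0.974 in the mutant-labelled library.

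**Figure D1:**
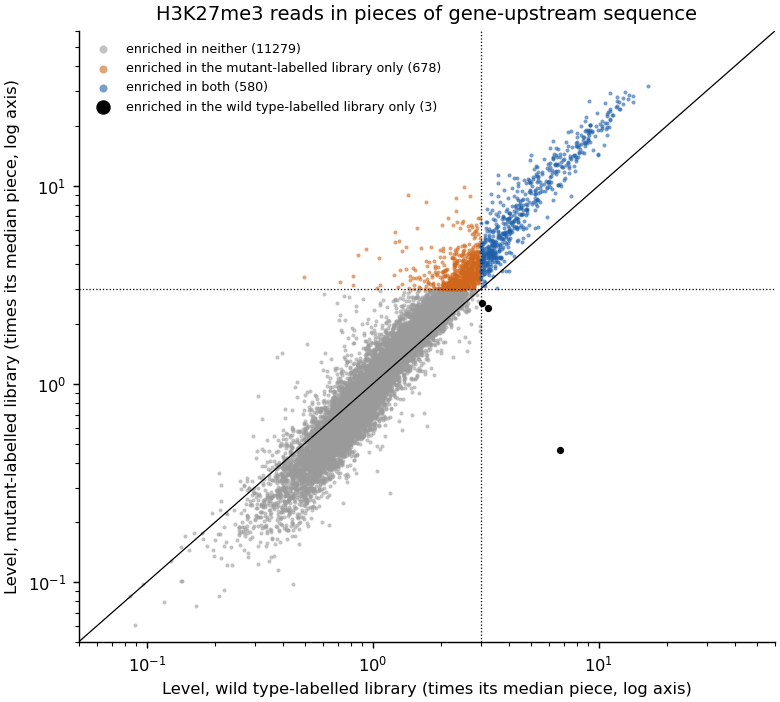
Level of each 2 kb piece in the wild type-labelled library (x axis) and the mutant-labelled library (y axis), in multiples of the median piece of the same library on log axes, with dotted lines at 3 and a solid line at equal levels. Points are pieces, 580 of them enriched in both libraries, 678 in the mutant-labelled library only and 3 in the wild type-labelled library only; 27 pieces with a level of 0 are not drawn.

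Several of the widest enriched domains in both libraries held genes for developmental transcription factors, among them srp, Abd-B, svp and Doc1. Domains are joined from pieces of upstream sequence, so their spans include bases that were not measured. In the wild type-labelled library the widest was the GATA factor region with srp (3R:11809874-11860307, 50.4 kb), followed by the Abd-B side of the bithorax complex (3R:12757336-12805517, 48.2 kb), svp, a nuclear receptor gene (44.2 kb), and the Doc T-box genes (44.2 kb). The next domain (X:18137318-18171265, 33.9 kb) held the window of CG15059 and, named outside the rule, that of the cytokine gene upd3. In the mutant-labelled library the widest was the zfh1 region (3R:26549809-26608979, 59.2 kb), followed by the bithorax domain (52.5 kb) and the srp domain (50.4 kb). Upstream of srp the level was 8.49 in the wild type-labelled and 19.2 in the mutant-labelled library, upstream of svp 5.05 and 9.24, and upstream of Doc1 11.1 and 21.3. The zfh1 window, upstream of a zinc finger homeobox gene, stood at 5.01 and 14.3, a log2 ratio of 1.22 (1.13 to 1.32). The window of Eaf6 (3L:5601401-5603400) led another wide domain of the mutant-labelled library and stood at 4.35 and 10.9. In all, 403 and 879 domains were found.

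**Figure D2:**
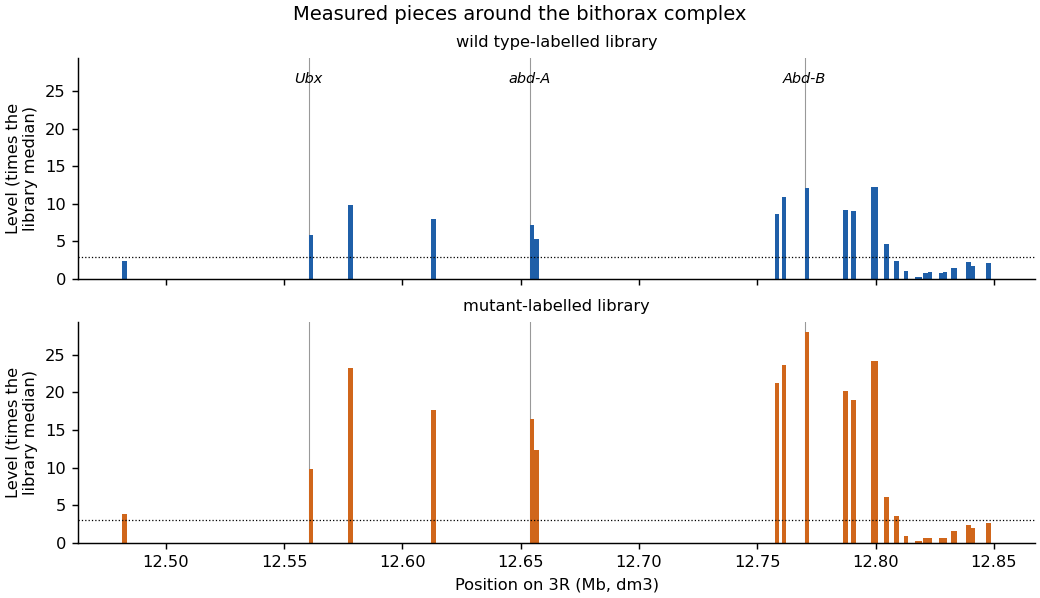
Level of the 24 measured pieces around the bithorax complex (x axis, 3R:12.48 to 12.85 Mb in dm3; y axis, multiples of the library median) in the wild type-labelled library (top) and the mutant-labelled library (bottom); grey lines mark the upstream windows of Ubx, abd-A and Abd-B, the dotted line is the enrichment threshold of 3, and gaps hold no measured sequence. The highest level is 12.3 in the wild type-labelled library, distal to the Abd-B window, and 28.0 in the mutant-labelled library, at that window, with 12 and 14 pieces enriched.

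At single genes, 11777 of 12442 upstream windows passed the minimum of 200 reads. With the totals as the scale, 453 genes were above 0.5, 3076 below -0.5 and 8248 between. Of the genes above, 347 stood at 3 or more times the median in the mutant-labelled library, whose reads also raise the ratio. In the wild type-labelled library 173 of the genes above were under 2 times the median. Most of the genes below carried little mark, 2650 of them under the median in the wild type-labelled library. The median over all genes was -0.24, since the marked minority took a larger share of the mutant-labelled reads. Scaling by pieces enriched in neither library raised each log2 ratio by 0.36 and gave 1775 genes above and 534 below. Scaling by the reads in enriched pieces, meaning pieces enriched in either library, moved each by -0.46 and gave 87 above and 8293 below. Single ratios between -0.36 and 0.46 therefore change sign under one of these scalings. List medians are given below also as the difference from the median of all genes, which these scalings do not move.

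Homeotic genes, which set segment identity, were marked in both libraries and stood higher in the mutant-labelled one. All 9 were enriched in each library, with a median level of 8.16 in the wild type-labelled and 16.6 in the mutant-labelled library. Of these, 8 were above 0.5, 0 below -0.5 and 1 between, but with scaling by the reads in enriched pieces 0 of the 9 were above. Abd-B (3R:12769992-12771991) had 3401 and 4589 reads, levels of 12.1 and 28.0 and a log2 ratio of 0.92 (0.86 to 0.99). For abd-A the ratio was 0.91 (0.83 to 0.995), for lab 0.70 (0.63 to 0.77) and for pb 0.56 (0.46 to 0.67), and Ubx, the member between, had 0.44 (0.33 to 0.54). The list median of 0.70 lay 0.94 above the median of all genes and at percentile 63.5 of random lists of equally marked genes, which became 8.22 with reads with no mismatch. Against the trend of the ratio with the level, the list median was -0.043, so homeotic genes did not exceed other genes of like level.

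Developmental regulators under Polycomb control behaved alike. Of 81 measured, 75 were enriched in the wild type-labelled and 78 in the mutant-labelled library, and 57 were above 0.5, 0 below -0.5 and 24 between. With scaling by the reads in enriched pieces 3 were above and 4 below. Their median level was 6.99 and 12.6, and their median log2 ratio was 0.64, which is 0.88 above that of all genes and at percentile 71.0 of matched lists, which became 51.1 with 1 read per position and strand. The spalt gene salm had a ratio of 1.05 (0.97 to 1.13), with levels of 8.79 and 22.3, and the retinal homeobox gene Rx 1.03 (0.91 to 1.14). Optix and inv, the members with the highest wild type levels (14.2 and 13.9), stood at 28.2 and 26.6 in the mutant-labelled library. The lowest members were tll at -0.15 (-0.35 to 0.05) and Poxn at -0.08 (-0.19 to 0.04), whose intervals include 0. Against the trend with the level, the list median was -0.033, at percentile 4.45.

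Of 3 measured Polycomb group genes that are themselves under Polycomb control, 2 were enriched in the wild type-labelled and 3 in the mutant-labelled library. The remaining genes of the Polycomb and Trithorax groups, except nej in the mutant-labelled library, were not enriched. Upstream of Su(z)2 the level was 7.54 in the wild type-labelled and 16.2 in the mutant-labelled library, with a log2 ratio of 0.81 (0.73 to 0.89), and upstream of ph-p 5.13 and 10.8, with 0.79 (0.68 to 0.89). Psc stood at 2.87 and 4.39, with 0.32 (0.17 to 0.47). These 3 genes, of which 2 were above 0.5, 0 below -0.5 and 1 between, had a median of 0.79, at percentile 93.1 of matched lists and 1.03 above all genes, but with scaling by the reads in enriched pieces 0 of the 3 were above. Of the 23 other Polycomb and Trithorax group genes, 1 was above 0.5, 11 below -0.5 and 11 between, with median levels of 0.779 and 0.652, and with scaling by pieces enriched in neither library 4 were above and 1 below. The one above was nej, the gene for the acetyltransferase CBP, at levels of 2.78 and 4.98 and a ratio of 0.55 (0.40 to 0.69). The lowest were pho at -0.87 (-1.24 to -0.51) and mor at -0.86 (-1.28 to -0.45). The median of -0.48 lay -0.24 from that of all genes, at percentile 17.98 of matched lists.

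Most genes of the germline and the piRNA pathway were not enriched. Of 21 measured germline genes 0 passed 3 times the median in the wild type-labelled library and 2 in the mutant-labelled library, ovo at levels of 2.67 and 3.70 and the anterior determinant bcd at 2.70 and 3.47, and of the piRNA genes 0 passed in either. Of 21 germline stem cell and oogenesis genes, 0 were above 0.5, 4 below -0.5 and 17 between, with median levels of 1.12 and 0.981. Scaled by pieces enriched in neither library, 2 were above and 2 below, and by the reads in enriched pieces 0 were above and 14 below. The list median of -0.26 lay -0.02 from that of all genes, at percentile 42.1 of matched lists. The translational repressor gene pum was highest at 0.44 (0.25 to 0.63), and the lowest were the sex determination gene Sxl at -1.02 (-1.44 to -0.62) and the posterior determinant osk at -1.01 (-1.39 to -0.64). Of 21 piRNA pathway genes, 0 were above 0.5, 6 below -0.5 and 15 between, at a median of -0.33, which is -0.09 from all genes and at percentile 89.4. The highest was del at 0.36 (0.14 to 0.58), the lowest was piwi itself, and Hen1 stood at -0.68 (-1.0007 to -0.37). With scaling by pieces enriched in neither library 0 of the piRNA genes were below and 4 above.

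Ovarian somatic and follicle cell genes were split. Of 20 measured, 5 were above 0.5, 2 below -0.5 and 13 between, with median levels of 2.05 and 2.78. EcR, the ecdysone receptor gene (2R:2019428-2021427), had 360 and 881 reads, levels of 1.28 and 5.37 and a log2 ratio of 1.78 (1.60 to 1.96). Also above were zfh1, mirr at 0.58 (0.49 to 0.68) and upd1 at 0.60 (0.53 to 0.67), the last with levels of 11.5 and 21.3. The yolk protein gene Yp3 was lowest at -0.78 (-1.15 to -0.42). The list median of 0.05 lay 0.29 above that of all genes, at percentile 39.2 of matched lists. With all windows of a gene together the median was -0.07 and the percentile 9.44, and with scaling by the reads in enriched pieces 2 were above and 9 below. Chorion and vitelline membrane genes, which follicle cells use to build the eggshell, had 1 of 14 above 0.5, 0 below -0.5 and 13 between, but 0 above and 11 below with scaling by the reads in enriched pieces. Their median levels were 1.81 and 1.95, and their median of -0.16 was 0.08 above all genes but at percentile 1.34 of matched lists, which became 4.51 with 1 read per position and strand and 16.9 with reads with no mismatch. Cp7Fb was the one above, at 0.54 (0.41 to 0.66), and Cp16 stood at -0.05 (-0.19 to 0.09). No input library was analysed here to separate DNA copy number from the mark in the levels of these eggshell genes.

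With scaling by totals, genes of other tissues were mostly between the call limits, and these counts depend on the scaling. Among 23 testis genes 2 were above 0.5, 1 below -0.5 and 20 between, with median levels of 1.53 and 2.14, and with scaling by pieces enriched in neither library 11 were above and 1 below. Their median of 0.11 lay 0.36 above all genes and at percentile 99.4 of matched lists. The mitofusin gene fzo stood at 7.31 and 18.7 with a ratio of 1.06 (0.98 to 1.15), bol at 0.96 (0.76 to 1.16), and the Cdc25 phosphatase gene twe at -0.88 (-1.31 to -0.46). Of 17 neuronal genes 1 was above 0.5, elav at 0.89 (0.80 to 0.98), 0 below -0.5 and 16 between, and the list median of -0.06 was 0.18 above all genes and at percentile 10.3. With scaling by pieces enriched in neither library 6 neuronal genes were above, and by the reads in enriched pieces 10 were below. All 16 muscle genes were between, with a median of -0.05, 0.19 above all genes and at percentile 94.5, but under these other scalings 4 were above and 9 below, respectively. Housekeeping genes had low levels, 0.744 and 0.646, with 0 of 29 above 0.5, 12 below -0.5 and 17 between, and their median of -0.48 was -0.24 from all genes and at percentile 63.3. With scaling by pieces enriched in neither library 3 of them were below. The lowest of these was alphaTub84B at -1.001 (-1.41 to -0.61). Of 6 heat shock genes 2 were above 0.5, 2 below -0.5 and 2 between, with a median of -0.21, 0.03 above all genes and at percentile 99.2. The genes above, Hsp70Bb and Hsp70Bbb, share 1 window, counted for each of them, near almost identical Hsp70 copies and are uncertain. With 1 read per position and strand 4 genes passed the minimum, 0 were above, the median was -0.37 and the percentile 78.8.

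**Figure D3:**
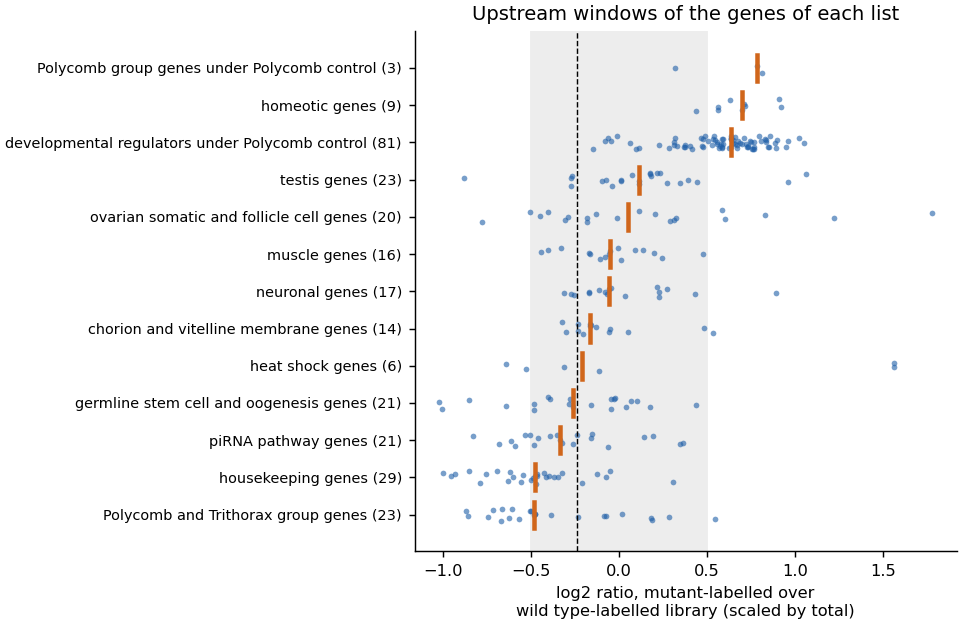
Log2 ratio (x axis) of each measured upstream window, mutant-labelled over wild type-labelled library, scaled by totals, for the genes of each fixed list (y axis, number measured in brackets). Blue points are genes, orange bars are list medians, the dashed line is the median of all genes at -0.24, and the grey band spans the call limits; homeotic genes (0.70) and developmental regulators (0.64) lie to the right of it and housekeeping genes (-0.48) to the left.

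Except for Map205, the 15 highest and 15 lowest windows lay under the enrichment threshold of 3 in the wild type-labelled library. Most windows did so, since 538 of all 12442 reached that threshold there. The highest log2 ratio was upstream of krz, the non-visual arrestin gene near the end of arm 3R (3R:27877716-27879715), with 139 and 562 reads, levels of 0.493 and 3.43 and a ratio of 2.504 (2.23 to 2.78). Next came the bestrophin gene Best4 (3L:15290058-15292057) at levels of 1.44 and 8.92 and a ratio of 2.34 (2.15 to 2.53), and the glutathione S-transferase gene GstD9 (3R:8193287-8195286) at 0.651 and 3.51 and a ratio of 2.14 (1.90 to 2.38). The transcription factor gene Atf3 followed at 2.07 (1.87 to 2.28), then RhoGAP1A at 1.94 (1.77 to 2.10), the cytochrome P450 gene Cyp6a20 at 1.90 (1.71 to 2.09), CG10562 at 1.81 and EcR. The remaining members of the 15 were CG13204, mthl8, CG43389, chb, COX7AL2, GstE3 and Coq2, the last at 1.57 (1.44 to 1.71).

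The lowest ratio was upstream of Map205, a gene for a microtubule-associated protein, also near the end of arm 3R (3R:27894164-27896163). Its window held 1711 reads in the wild type-labelled and 68 in the mutant-labelled library, levels of 6.77 and 0.462 and a log2 ratio of -4.16 (-4.54 to -3.81). It was followed by CG9380 near the end of arm 2R (2R:21142842-21144841), with 318 and 44 reads and a ratio of -2.36 (-2.85 to -1.91), the transcription factor gene cbt at -2.003 (-2.59 to -1.45), the serine protease gene Ser6 at -1.77 (-2.10 to -1.46) and CG17574 at -1.67 (-1.98 to -1.38). The cohesin subunit gene SMC1 stood at -1.58 (-2.07 to -1.11). Among the other members of the 15 lowest, Scsalpha2, Sdhaf3, Rlb1, CG10365, Xe7, GrlHz, Pez and psq lay between -1.48 and -1.41. Of the genes below -0.5, 3 had a level of 3 or more in the wild type-labelled library.

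**Figure D4:**
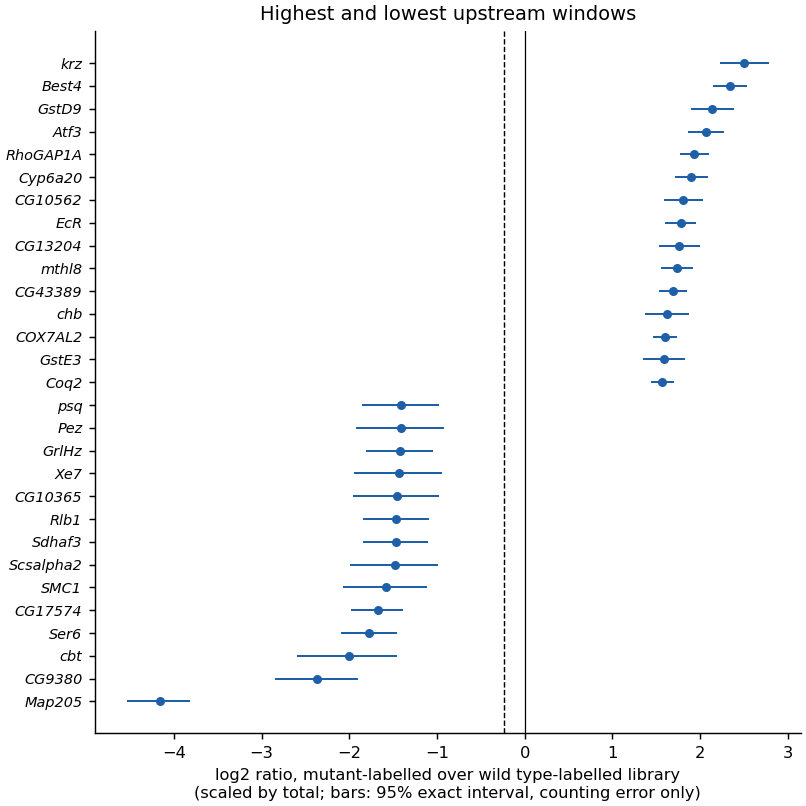
Log2 ratio (x axis) of the 15 highest and 14 of the 15 lowest upstream windows (y axis, gene symbols), mutant-labelled over wild type-labelled library, scaled by totals; points are single values from 1 library per group and bars are exact 95% intervals that cover counting error only. The dashed line is the median of all genes at -0.24, and the values run from -4.16 at Map205 to 2.504 at krz.

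The chromosome arms held nearly equal shares of the reads in both libraries, with the small arm 4 standing apart. Arm 4, much of which is heterochromatic, held 0.720% (0.712 to 0.728%) of the reads in the wild type-labelled and 0.834% (0.824 to 0.844%) in the mutant-labelled library, a log2 ratio of 0.21. In pieces enriched in neither library that ratio was 0.0098. On arm X the shares were 16.5% and 16.9% (log2 ratio 0.036) and on 3L 18.8% and 18.3% (-0.039). The log2 ratios of 2L, 2R and 3R were -0.0066, -0.0028 and 0.0055.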

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

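The tandem repeat units named here were those with the most reads over both libraries, so all of these values were chosen after the result was seen.

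Apart from the placed reads, each library held reads made of short tandem repeats, which no comparison of the report covers. Units are written in the first alphabetical rotation of either strand, and units of 1 or 2 bases were not counted. The AAGAG satellite took 0.918% of the wild type-labelled and 0.867% of the mutant-labelled reads. For AAGAC the shares were 0.178% and 0.150%, for AACAC 0.183% and 0.130%, and for AAGGAG 0.0692% and 0.0759%. AAGGC stood apart from these with 0.115% and 0.0493%, a ratio of 0.430 (exact interval 0.423 to 0.437, counting error only) of the mutant-labelled over the wild type-labelled share. Among units with fewer reads, ACCAGTACGGG went the other way, with 0.04725% and 0.0741%, a ratio of 1.57 (1.54 to 1.60). The scale of the report is the reads left on the main arms after masking. Per such read, the ratio of mutant-labelled over wild type-labelled was 1.27 for AAGAG and 1.13 for AAGAC. It was 0.958 for AACAC, 0.579 for AAGGC and 1.48 for AAGGAG. Per read sequenced the ratios were 0.944, 0.842, 0.712, 0.430 and 1.097 in the same order. The side of 1 therefore depends on which of these scales is used for AAGAG and AAGAC. Masking took a larger part of the placed mutant-labelled reads, which raises the ratios on the scale of the report. No explanation was tested for these values, and no input library was analysed here to separate repeat copy number from the mark.

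Reads that matched the upstream set at more than 1 place, and were left out of the comparison for that reason, made up 3.13% of the wild type-labelled and 3.88% of the mutant-labelled reads. Per read sequenced this is 1.24 times as many in the mutant-labelled library (1.235 to 1.240). Per read left on the main arms after masking it is 1.67 times (1.662 to 1.669).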

How the results depend on the processing

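The settings chosen after the result was seen were bins of 1 kb, bins of 5 kb (the size planned at first, run as an alternative once 2 kb was in use), reads with no mismatch, no repeat mask, all windows of a gene together and the difference from the trend with the level, and the window of each gene was held fixed over the settings after a first run had picked it anew in each. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The planned window of 2.5 kb on both sides of the gene start was not run, since the sequence downstream of starts was not at hand. Pieces of 2 kb became the size used throughout, in place of the planned 5 kb bins. Among the lists, reads with no mismatch left 2 measured heat shock genes, too few for a percentile.

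The order of the libraries in enriched bins and in the share of reads held under each setting run. The counts for the wild type-labelled and mutant-labelled library were 1846 and 2907 at 2 times the median, 217 and 460 at 5 times, 369 and 656 with 10 kb bins, 376 and 664 with 5 kb bins, and 1501 and 2969 with 1 kb bins. The 10 kb and 5 kb bins are merged stretches divided at up to that length and never joined, so these settings hardly differ from each other. With 1 read per position and strand the wild type-labelled count was 342. The shares of reads in these bins were 35.4% and 56.8% at 2 times, 9.70% and 23.2% at 5 times, 13.9% and 28.8% with 10 kb bins, 14.2% and 29.04% with 5 kb bins, 21.9% and 43.3% with 1 kb bins, 8.86% and 24.8% with 1 read per position and strand, and 28.3% and 50.5% with no repeat mask. Thinning the wild type-labelled library to the depth of the other gave it a share of 17.5%.

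Of the wild type-labelled enriched bins, 98.4% were enriched in the other library at 2 times the median. Of the mutant-labelled ones, 62.5% were shared at 2 times, 56.1% with 10 kb bins, 56.5% with 5 kb bins, 50.0% with 1 kb bins, 36.4% with 1 read per position and strand, and 40.7% when a domain was shared by at least 50% of its length. Pearson's r was 0.967 with 10 kb bins, 0.967 with 5 kb bins, 0.958 with 1 kb bins, 0.962 with 1 read per position and strand, 0.988 with no repeat mask and 0.955 on log2 values with a pseudocount of 1 read. Spearman's rho was 0.959 with 10 kb bins, 0.959 with 5 kb bins, 0.942 with 1 kb bins and 0.951 after thinning.

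The log2 ratio of arm shares with 1 read per position and strand was -0.0227 for 3L, -0.00393 for 3R, which turned sign, 0.0260 for X 0.151 for arm 4, and 0.00248 for 2R, a turn of sign within its counting interval. In bins enriched in neither library 2L (0.00202), 2R (0.000134, within its counting interval), 3L (0.00722) and 3R (-0.0112) turned sign, X stood at 0.00597 and arm 4 at 0.00976. For the arms and for the shares and overlaps above, the cause was not tested.

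Scaling set the number of genes called. By the median of bins not enriched, 1775 were above 0.5 and 534 below -0.5, so 76.9% of calls were above against 12.8% in the main setting, and by the reads in enriched bins 87 and 8293, or 1.04% above. In the first of these settings the list medians were 1.06 for homeotic genes, 1.0 for developmental regulators, 1.15 for Polycomb group genes under Polycomb control, 0.10 for germline genes, 0.0314 for piRNA genes, 0.42 for ovarian somatic genes, 0.20 for chorion genes, 0.48 for testis genes, 0.31 for neuronal genes, 0.31 for muscle genes and -0.11 for housekeeping genes. By the reads in enriched bins they were 0.24 for homeotic genes, 0.18 for developmental regulators, -0.94 for Polycomb and Trithorax group genes, -0.72 for germline genes, -0.79 for piRNA genes, -0.40 for ovarian somatic genes, -0.62 for chorion genes, -0.34 for testis genes, -0.51 for neuronal genes, -0.51 for muscle genes, -0.93 for housekeeping genes and -0.67 for heat shock genes. These shifts follow from the construction of the scaling. Scaled by the reads in enriched bins, 0 of 9 homeotic genes, 3 of 81 developmental regulators and 0 of 3 Polycomb group genes under Polycomb control were above 0.5, and 18 of 23 Polycomb and Trithorax group genes, 14 germline, 17 piRNA and 28 housekeeping genes were below -0.5. The percentiles among matched lists also moved with the setting. Reads with no mismatch gave 8.22 for homeotic genes, 68.5 for Polycomb and Trithorax group genes and 16.9 for chorion genes. All windows of a gene together gave 46.9 for developmental regulators and 9.44 for ovarian somatic genes. The neuronal percentile became 32.4 with 1 read per position and strand and 47.9 with all windows together. For housekeeping genes it became 31.5 with no read minimum, 91.9 with all windows together and 18.15 against the trend with the level. Testis genes stayed at percentile 97.7 or more. The cause of these moves was not tested. The ovarian somatic median also turned sign with no read minimum (-0.00926), with no repeat mask (-0.0850) and with all windows of a gene together (-0.0698). The neuronal median turned sign with 1 read per position and strand (0.0869) and with reads with no mismatch (0.0129). The muscle median turned sign with 1 read per position and strand (0.0328).

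The difference from the trend with the level took away the part of each ratio that genes of like level share, and 183 genes were then below -0.5 and 464 above, 210 of the latter shared with the main setting. The medians of homeotic genes (-0.0430), developmental regulators (-0.0334), Polycomb and Trithorax group genes (0.0157), germline genes (0.0107), piRNA genes (0.13), ovarian somatic genes (-0.0459), neuronal genes (0.0254), muscle genes (0.14) and heat shock genes (0.35) turned sign, while Polycomb group genes under Polycomb control stood at 0.14 and housekeeping genes at -0.0489. Among named genes lab (-0.13), inv (-0.25), Optix (-0.21), mirr (-0.0555), upd1 (-0.21), VhaM9.7-d (-0.19), Doc1 (-0.16), opa (-0.0541), so (-0.21), mod(mdg4) (-0.0280), C15 (-0.0933) and E5 (-0.0370) turned sign, by the construction of that setting. Without the repeat mask 315 genes were above 0.5 and 4517 below -0.5, against 453 and 3076 in the main setting. The medians were then 0.56 for homeotic genes, 0.49 for developmental regulators, -0.29 for chorion genes, -0.18 for neuronal genes and -0.19 for muscle genes. The testis median turned sign without the mask, to -0.0213. With reads with no mismatch the homeotic median was 0.56, and with 1 read per position and strand the developmental regulator median was 0.54; the cause was not tested. Of 989 values for single named genes, 604 stayed within the counting interval of the main value, 373 moved out of it and 12, the called genes listed above, turned sign. A further 50 values of genes not called turned sign, 15 of them with scaling by the reads in enriched bins and 12 with scaling by the median of bins not enriched. Depth limits weakly covered windows most, since a window with 200 reads cannot show a fold below about the width of its interval.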

Other observations

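The gene families and arm-end windows, the tests of PCR duplicates and of a uniform background, the tests of loss of the mark and of rare 20-mers upstream of w, and the tests of duplicates and of a DNA duplication in the top windows were chosen after the result was seen.

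Several glutathione S-transferase windows stood higher in the mutant-labelled library. This and the other families were looked at because GstD9, GstE3 and Cyp6a20 were among the highest windows, so their values are description only, and no percentile among matched lists is given for them. Among 33 glutathione S-transferase genes, 10 were above 0.5, 6 below -0.5 and 17 between, with median levels of 0.866 in the wild type-labelled and 1.34 in the mutant-labelled library. Their median log2 ratio lay 0.33 above that of all genes. The highest sat in clusters with overlapping windows, GstD9 (2.14) and GstD10 (1.46) on 3R, and GstE3 (1.59), GstE10 (1.57) and GstE2 (1.55) on 2R, so they are fewer independent loci than genes. GstZ2 (0.56) on 3R and GstT3 (0.54) on X lay elsewhere, while GstT1 stood at -0.89 and GstO1 at -0.82. Of 73 cytochrome P450 genes 5 were above 0.5, 10 below -0.5 and 58 between, with Cyp6a20 and its neighbour Cyp6a9 (1.25, 1.04 to 1.46) the highest, and the family median was 0.16 above all genes. UDP-glycosyltransferase genes, a further detoxification family, had 0 of 28 above 0.5, 3 below -0.5 and 25 between, and a median 0.05 above all genes. Odorant and gustatory receptor genes (2 of 26 above 0.5, 3 below -0.5, 21 between) lay 0.17 above all genes, and ribosomal protein genes (2 of 79 above 0.5, 26 below -0.5, 51 between) at -0.14 from all genes.

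Windows near the ends of the chromosome arms held several of the most extreme ratios in both directions. Of 27 windows within 100 kb of an arm end 5 were above 0.5, 4 below -0.5 and 18 between, and the set was picked because extreme windows lay there. On 3R, mod (0.606 and 2.82, log2 ratio 1.93) and krz lay within about 20 kb of Map205, the lowest of all genes. On the other arms mthl8 (3L) at 1.73, CG13405 (3L) at 1.28 and RhoGAP1A (X) at 1.94 were above, and galectin (2L) at -1.17, CG30429 (2R) at -1.12 and CG9380 (2R) at -2.36 below. Only Map205 and w, of windows with at least 100 reads in one library and 1.5 kb unmasked, held under 10% of the scaled reads in the other library. The 2 windows differ in kind. At Map205 the mutant-labelled level of 0.462 lay above the 1st percentile of that library's pieces (0.189), and the wild type-labelled level was high at 6.77. At w the mutant-labelled level was 0.0366, under that percentile. No explanation was tested for Map205.

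The higher contrast between marked and other windows in the mutant-labelled library was weighed against technical explanations. The contrast ratio, the median over 81 developmental regulators of the mutant-labelled over the wild type-labelled level, was 1.90 (quartiles over genes 1.70 and 2.06). It was 1.68 with 1 read per position and strand and 1.73 against pieces of the same class of GC content. These values argue against PCR duplicates and GC content as the whole cause. The ratio was 1.90 with the wild type-labelled reads thinned. Random thinning lowers a window and the library median alike, so this value could hardly move and does not decide on depth. A uniform background in the wild type-labelled library would keep its lowest pieces near a floor, but their observed level was 0.471 (bootstrap interval 0.446 to 0.495) of the one predicted from enriched pieces. A lower pull-down efficiency with a background that varies along the genome, a different mix of cell types in mutant ovaries and an effect of piwi all stay open as hypotheses, since each could raise marked genes by level as seen, and 1 library per group cannot separate them.

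The near-empty window upstream of w may reflect missing DNA, changed sequence or a mark lost from DNA that is present. The upper 95% counting limit of its level in the mutant-labelled library was 0.0796, under the 1st percentile of that library's pieces (0.189) and under the lowest level (0.0980, median 0.356) of the 518 other pieces with a wild type-labelled level within 10% of its own 0.454, which argues against loss of the mark from DNA that is still present. For sequence differences that keep reads from matching, the test set before the result found 1.1 times the expected number of reads sharing a 20-mer with the window, which met its bound of 0.5 for a cause, and it was set aside only after that value was seen, because 917 such reads in the wild type-labelled library against 128 placed there show that most came from elsewhere. The test on 20-mers rare elsewhere, added then, gave 0.480 (0.366 to 0.623), an interval that includes the same bound. It counted 228 reads in the wild type-labelled library, against 128 placed, and 78 in the mutant-labelled library, against 6 placed. Reads from elsewhere can remain in both counts, so this ratio does not decide on sequence differences either. Sequence differences and missing DNA therefore both stay open, and an exchange of the strain labels cannot be excluded.

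For the 15 windows with the largest gain, 3 technical explanations were tested. Reads from a diverged repeat copy would bring mismatches. The share of reads with a mismatch differed by a median of -1.94 percentage points (range -11.2 to 9.57), mutant-labelled minus wild type-labelled library. An identical copy outside the measured set would bring no mismatches, and steps rich in reads with 2 mismatches had been masked. The median therefore does not decide on reads from another repeat copy. With 1 read per position and strand the median log2 ratio was 1.61, which argues against PCR duplicates at a few positions as the cause over the set. The median fold was 4.20 (3.64 to 6.95), but the windows were chosen for a high fold, so it does not decide on a duplication of the DNA in the mutant strain. Strain differences at single windows, such as an insertion nearby, could also account for some of them, were not tested and stay open beside an effect of piwi.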
